A study of Rattus norvegicus with 36 samples.

How the data were processed

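Male Sprague Dawley rats, 7 weeks old at the start, received DBDPE in corn oil by gavage (5 ml/kg) on 5 consecutive days, and the left lobe of the liver was collected 1 day after the last dose. RNA was hybridised to Affymetrix 3′ IVT arrays, with 6 samples at each of 970, 97.1, 9.71, 0.97 and 0.1 mg/kg and 6 vehicle samples. Per the submitters' processing notes, the authors used RMA and the affy package, whose versions are not stated. The deposited values are log2 signals per probe set, background-corrected and quantile-normalized, with no centring across samples, and whether arrays of another series were normalized with them is not stated. The values lie between 1.80 and 14.68, and 0 are missing. The table holds 31099 probe sets, of which 57 controls were left out. The labels number the samples within a group, and each was taken to come from its own rat. Residuals of samples with the same number in different groups correlated at a mean r of 0.0048 over 90 pairs. Single pairs ranged from -0.25 to 0.26, with 15 pairs over 0.1. The number was not used to pair the samples, except as a block in an alternative.

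Gene names come from the platform annotation, and 20758 of the 20826 probe sets that name 1 gene have an Entrez ID in the rat RefSeq gene table, which was used for names and neighbouring genes. The annotation names no genome build, so no positions are given. The RNA quality measure used, the log2 difference between the 3′ and 5′ beta-actin controls, lay between 1.02 and 1.33, with 1.12 ± 0.07 (SD, n = 6) in vehicle and 1.19 ± 0.08 (SD, n = 6) at 970 mg/kg. The same difference for the Gapdh controls was -0.09 ± 0.02 (SD, n = 6) in vehicle and -0.06 ± 0.03 (SD, n = 6) at 970 mg/kg. The arrays also hold hexokinase controls, and neither of these was used as a covariate.

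The groups, comparisons, gene lists and alternatives were fixed before the data were examined, apart from those named as chosen later. The series describes a comparison of vehicle with each dose at a false discovery rate under 5%. Here each dose was compared with vehicle in a linear model over all 36 samples with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), two-sided, with Benjamini-Hochberg adjustment within a comparison and a threshold of 0.05. A moderated F test covered the 5 doses together, and a slope on the dose step (0 for vehicle, 1 to 5 for the doses) tested for a trend. No filter on low values was applied. The comparison of the top doses with each other and the exact permutation tests of single genes and list scores were added after the results were seen.

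For gene groups, 31 lists of 446 distinct genes were fixed from general knowledge of liver biology, 394 of them measured. They cover nuclear receptor and stress response targets, lipid, bile acid and hormone pathways, the cell cycle, inflammation, and markers of liver and neighbouring cell types. Each gene was taken by its probe set of highest mean. The lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 31 lists, and again with an estimated correlation and with fry. Camera compares a list with the other genes, whereas fry asks whether its genes move one way. Members were also tested with limma adjusted over the list alone. That adjustment does not allow for the 31 lists, of which chance gives about 1 in 20 a passing member. Lists with such a member numbered 1 at each of the 3 lowest doses, 3 each at 97.1 and 970 mg/kg, and 4 for the trend. A list score is the mean log2 difference of the members from the vehicle mean. Lists share some genes, such as Cyp1a2 in the AhR and pericentral lists and Nqo1 in the AhR and Nrf2 lists.

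Genes were named by a fixed rule: up to 10 genes per direction past the threshold, the genes of smallest p to make 3 where fewer than 5 passed, the 20 panel genes at 970 mg/kg, and up to 4 members per list, preferring those past the threshold over the list alone. Exceptions are named as chosen after their values were seen.

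The alternatives were the replicate number as a block, centred arrays, cyclic loess, array weights, an intensity trend with a robust prior, variances without moderation, the beta-actin difference as a covariate, the mean of a gene's probe sets, the probe sets at or above the median mean level, the 12 samples compared alone, adjustment over all 5 doses together, thresholds of 0.01 and 0.1, the dose in mg/kg, the slope without vehicle, and each sample left out. Lists without Cyp1a1 and Cyp1a2 and an exact permutation test of each list score were added after seeing the data. The method was tested on simulated data of the same size: at 970 mg/kg limma recovered 94% of 50 probe sets changed 1.5-fold and 100% of 50 changed 2-fold, with 9 false calls in that run and 16 in the trend run, and camera recovered 10 of 10 lists shifted by 0.2 with 0 of 50 false calls at either correlation. In simulated lists the genes varied independently, unlike those of real lists. In the simulated run for probe sets, 50 each were changed 1.5-fold, 2-fold, 4-fold and 11-fold at once. Many true changes ease the adjusted threshold, so the recovery of a lone 1.5-fold change can be lower than given here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.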

Results

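Liver RNA was measured on microarrays in 36 male rats that had been given decabromodiphenylethane (DBDPE), a brominated flame retardant, or its corn oil vehicle by mouth on 5 consecutive days. The 6 groups of 6 animals received vehicle alone or 970, 97.1, 9.71, 0.97 or 0.1 mg/kg DBDPE per day. Each animal gave 1 array of 31042 probe sets, of which 20826 name 1 gene, 436 name several and 9780 name none, so that 14217 distinct genes were measured. Across probe sets, which are not independent replicates, pairs of arrays correlated at r = 0.993 to 0.997, and array medians lay between 5.07 and 5.12 on the log2 scale. The first principal component held 8.64% of the variance over the 36 arrays, and 7.18% of its variance lay between the dose groups; the next components held 7.55% and 6.80%, with 26.3% and 20.6% between the groups. The mean distance between arrays was 42.1 for pairs within a group and 42.4 for pairs from different groups. The number of arrays limits the precision: at each dose the median probe set had a 95% interval of 0.16 on either side of its log2 fold change.

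The comparison of 970 mg/kg with vehicle asks which liver transcripts change at the highest dose. Cyp1a1 and Cyp1a2, the cytochrome P450 genes classically induced through the aryl hydrocarbon receptor (AhR), rose, and no other probe set of the 31042 passed the limma test. Cyp1a1 went from a log2 level of 4.57 ± 0.15 (SD, n = 6) in vehicle to 10.81 ± 0.63 (SD, n = 6) at 970 mg/kg. This is a log2 fold change of 6.23 (95% interval 5.66 to 6.80), or 75.2-fold, with a limma adjusted p of 9.190e-18. The vehicle level lies below every array median, so background signal may make this fold too small. Cyp1a2, which is abundant in untreated liver, went from 12.81 ± 0.14 (SD, n = 6) to 13.67 ± 0.08 (SD, n = 6), a log2 fold change of 0.86 (95% interval 0.74 to 0.99), or 1.82-fold, with a limma adjusted p of 9.909e-12. For both genes 6 of 6 treated animals lay above every vehicle animal, and the exact permutation test gave p = 0.00216 for each (two-sided, the smallest p that 6 against 6 can give; 0.00433 after adjustment over 12 such tests). The measured genes nearest to Cyp1a1 and Cyp1a2 on the chromosome had log2 fold changes of 0.01 (Csk) and 0.05 (Cplx3) on the Cyp1a2 side and -0.14 (Edc3), -0.05 (Clk3), -0.05 (Arid3b) and -0.04 (Ubl7) on the other, none past the threshold. At 970 mg/kg 1513 probe sets had an unadjusted p under 0.05, against 1552.1 expected by chance. The 95% interval lay within -1 to 1 for 99.5% of probe sets and excluded changes of the signal beyond 1.5-fold for 97.8%. No filter on low values was applied, so for probe sets near background a narrow interval does not exclude a change of the transcript.

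**Figure D1:**
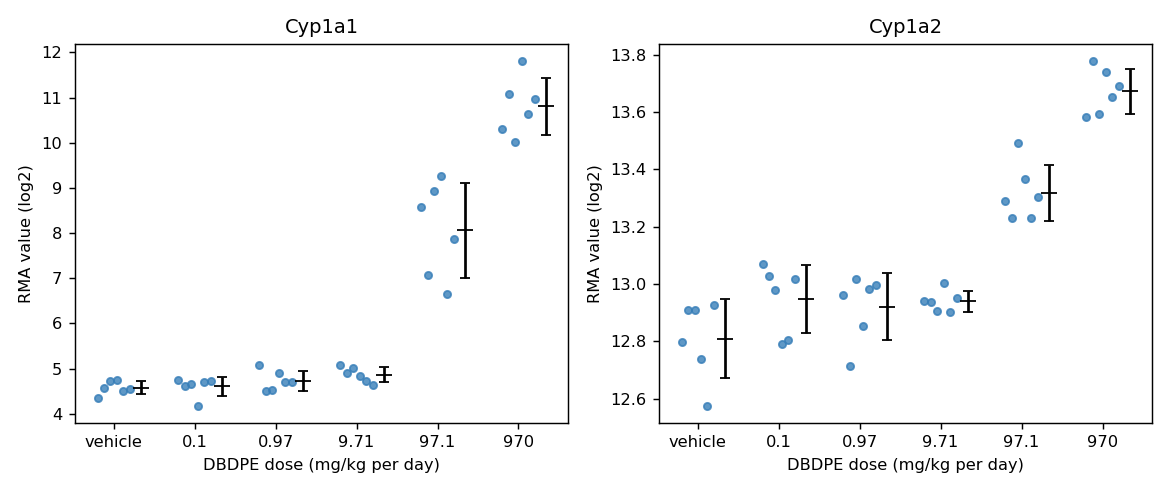
Log2 level of Cyp1a1 and Cyp1a2 (vertical axes) in each of the 36 animals by DBDPE dose in mg/kg (horizontal axes), with the mean and SD of the 6 animals of each group. Mean Cyp1a1 lay at 4.57 in vehicle, 8.06 at 97.1 mg/kg and 10.81 at 970 mg/kg, and mean Cyp1a2 at 12.81, 13.32 and 13.67.

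A panel of 20 liver genes chosen in advance, 18 of them measured by a probe set of their own, held no other gene past the threshold at 970 mg/kg. Nqo1, a quinone reductase gene driven by AhR and by the oxidative stress factor Nrf2, had a log2 fold change of 0.68 (95% interval -0.02 to 1.38). Hmox1, the heme oxygenase gene, had 0.26 (0.08 to 0.44), with 6 of 6 treated animals above every vehicle animal. Cyp3a23-3a1, a gene induced through the pregnane X receptor (PXR), had 0.20 (0.02 to 0.39). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had -1.07 (-1.85 to -0.30) with an adjusted p of 0.966. The remaining panel genes had log2 fold changes of 0.36 (Mki67), 0.24 (Abcc3), 0.16 (Ugt2b1), 0.08 (Cdkn1a), 0.05 (Ephx1), 0.04 (Acot1), 0.01 (Cyp2c11), -0.08 (Cyp4a1), -0.09 (Por), -0.17 (Dio1), -0.22 (Fasn) and -0.32 (A2m). Cyp2b1, a standard marker of the constitutive androstane receptor (CAR), had no probe set of its own; the probe set shared by Cyp2b2 and Cyp2b1 had 0.27 (-0.17 to 0.72). The smallest p among the other genes belonged to Cyb5a, the microsomal electron donor cytochrome b5, at 0.17 (0.10 to 0.24, adjusted p = 0.327), with 6 of 6 treated animals above every vehicle animal, and to Vamp1 at -0.36 (adjusted p = 0.351), Bicral at -0.39 and Depp1 at -0.99, none past the threshold. The Cyb5a log2 fold change at 970 mg/kg passed under 4 alternatives, such as variances not moderated across genes or an intensity trend with a robust prior (adjusted p from 0.00153 to 0.0378). Without vehicle replicate 4, Vamp1 passed at -0.44 (limma adjusted p = 0.00310). Its 2 other probe sets had -0.07 and -0.04 in all samples (limma adjusted p of 0.979 or more).

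**Figure D2:**
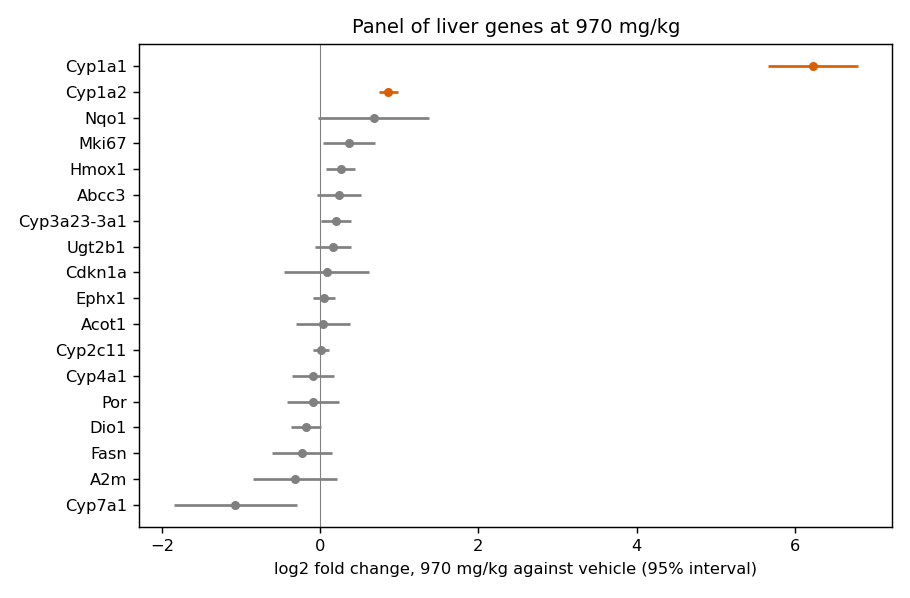
Log2 fold change at 970 mg/kg against vehicle (horizontal axis) of the 18 measured panel genes (vertical axis), with bars for the 95% interval from 6 animals per group and orange for an adjusted p under 0.05. Cyp1a1 at 6.23 and Cyp1a2 at 0.86 are the genes in orange, and Cyp7a1 has the lowest value, -1.07.

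Genes of the cell cycle were higher as a group at 970 mg/kg. Of the 26 members measured, 24 had a value above 0, with a median log2 fold change of 0.28. Adjusted over the list alone, 12 members rose, and over all probe sets tested 0 of the 26 did. Those that rose included the mitotic cyclins Ccnb1 (0.65), Ccnb2 (0.62) and Ccna2 (0.59) and the kinase gene Cdk1 (0.51). The G1 cyclin Ccnd1 had -0.21, and Pcna and Tyms of DNA synthesis had 0.05 and -0.09. The list passed limma's camera with its preset correlation (adjusted p = 9.213e-18 over 31 lists) and also with an estimated correlation (adjusted p = 0.0457) and by fry (adjusted p = 0.0467). The mean score of the list was 0.28 ± 0.27 (SD, n = 6) at 970 mg/kg against 0 ± 0.08 in vehicle, and 5 of 6 treated animals lay above every vehicle animal. An exact permutation test of that score gave p = 0.0368, or 0.278 after adjustment over the 31 lists, where a lone list cannot go below 0.0671, and without replicate 3 of the 970 mg/kg group, the animal of highest score, the difference was 0.20 with an exact p of 0.0671. The neutrophil marker score of the same animal, 0.94, was the highest of its group.

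**Figure D3:**
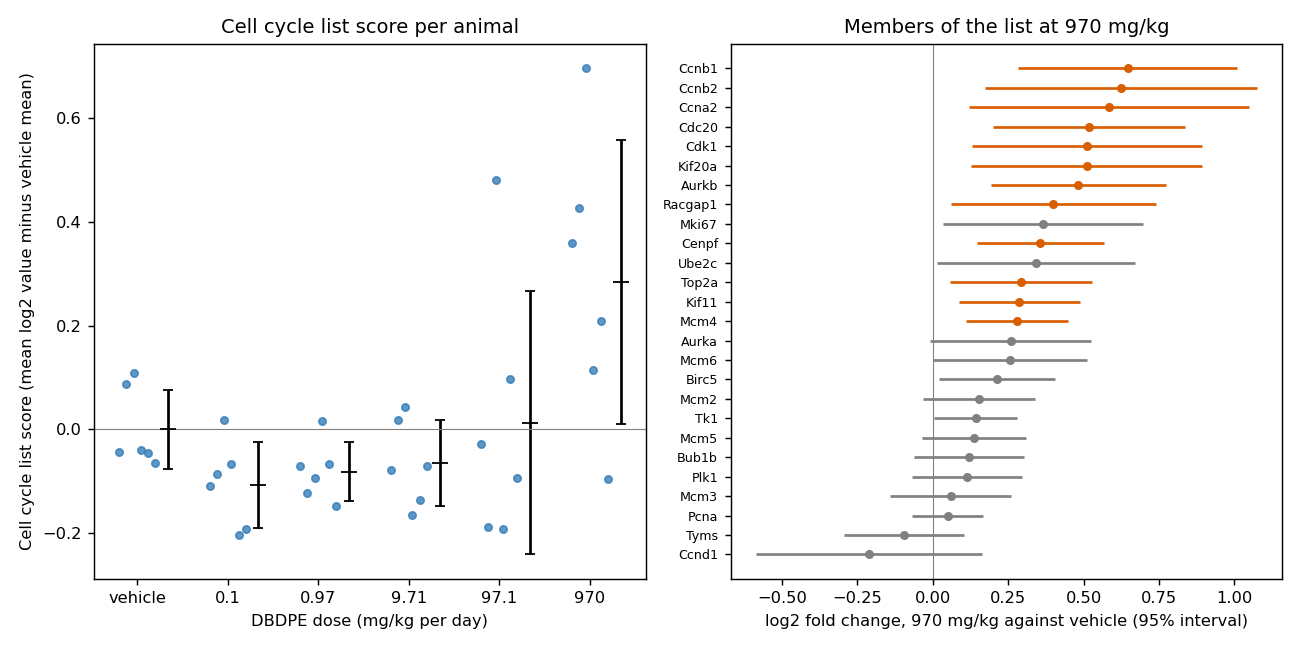
Left, mean log2 score of the cell cycle list relative to vehicle (vertical axis) in each animal by DBDPE dose in mg/kg, with the mean and SD of the 6 animals of each group; right, log2 fold change at 970 mg/kg of the 26 members with its 95% interval, in orange where past the threshold adjusted over the list alone. Group means lie between -0.11 and 0.01 up to 97.1 mg/kg and at 0.28 at 970 mg/kg, and 12 members are in orange.

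The AhR list rose at 970 mg/kg (adjusted p = 3.764e-13, and 1.186e-06 with an estimated correlation), with Cyp1a1 and Cyp1a2 as the 2 of 8 members that rose. The other 6 AhR members had a median log2 fold change of 0.15, from -0.08 to 0.68, and did not pass as a group (camera p = 0.0530, and 0.0927 with an estimated correlation). The pericentral hepatocyte list passed both tests (adjusted p = 2.746e-05, and 0.0457 with an estimated correlation), but of its 7 members Cyp1a2 alone rose, and Slc1a2 and Oat had 0.24 and 0.28. Without Cyp1a1 and Cyp1a2, an alternative chosen after seeing the data, no list passed with an estimated correlation, and the cell cycle list had an adjusted p of 0.137 there. The cell cycle list holds neither gene, so its values were unchanged. Its adjusted p rose only because other lists lost their small p in the adjustment over lists. In all, 9 of 31 lists passed at the preset correlation and 3 at the estimated correlation. Interferon response genes had a median of 0.32 with 19 of 21 above 0 (Usp18 0.94, Herc6 0.38; adjusted p = 2.357e-05, and adjusted p = 0.517 with an estimated correlation). Macrophage markers had 0.19 with 11 of 12 above 0 (Clec4f 0.28, Ptprc 0.24; adjusted p = 0.00385, and adjusted p = 0.517 with an estimated correlation). CAR and PXR targets, genes of drug metabolism and transport, had 0.05 with 15 of 18 above 0 (Cyp3a23-3a1 0.20, Ces2c 0.17; adjusted p = 0.00848, and adjusted p = 0.232 with an estimated correlation). Nrf2 targets had 0.08 with 14 of 19 above 0 (Hmox1 0.26, Abcc4 0.27; adjusted p = 0.0106, and adjusted p = 0.273 with an estimated correlation). Fatty acid synthesis genes had -0.12 with 5 of 20 above 0 (Acaca -0.22, Pklr -0.26; adjusted p = 0.0118, and adjusted p = 0.517 with an estimated correlation). T and NK cell markers had 0.07 with 9 of 12 above 0 (Klrd1 0.25, Prf1 0.36; adjusted p = 0.0324, and adjusted p = 0.424 with an estimated correlation).

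The other 22 lists did not pass at 970 mg/kg, with adjusted p between 0.152 and 0.884. Among the metabolic lists the median log2 fold change was -0.02 for PPARalpha targets, 0.01 for sterol synthesis, -0.01 for bile acid synthesis and transport, -0.06 for thyroid hormone response, -0.07 for glucocorticoid and fasting response and 0.02 for the sex-biased and growth hormone genes. Among the stress and inflammation lists it was -0.07 for the unfolded protein response, 0.03 for p53 targets, -0.004 for heat shock, 0.01 for the acute phase, 0.02 for metallothionein and iron and 0.01 for the circadian clock. Among the cell type lists it was -0.01 for hepatocyte and for periportal markers, -0.07 for endothelial, -0.03 for stellate cell and fibroblast, 0.07 for bile duct, 0.09 for B cell, 0.07 for neutrophil and 0.07 for erythroid markers. Pancreatic acinar markers had -0.02 and adipocyte markers 0.03. For the acute phase, adipocyte, circadian, metallothionein and pancreatic lists the median and the mean had opposite signs. The test pointed the way of the mean for the circadian, metallothionein and pancreatic lists and the way of the median for the acute phase and adipocyte lists.

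**Figure D4:**
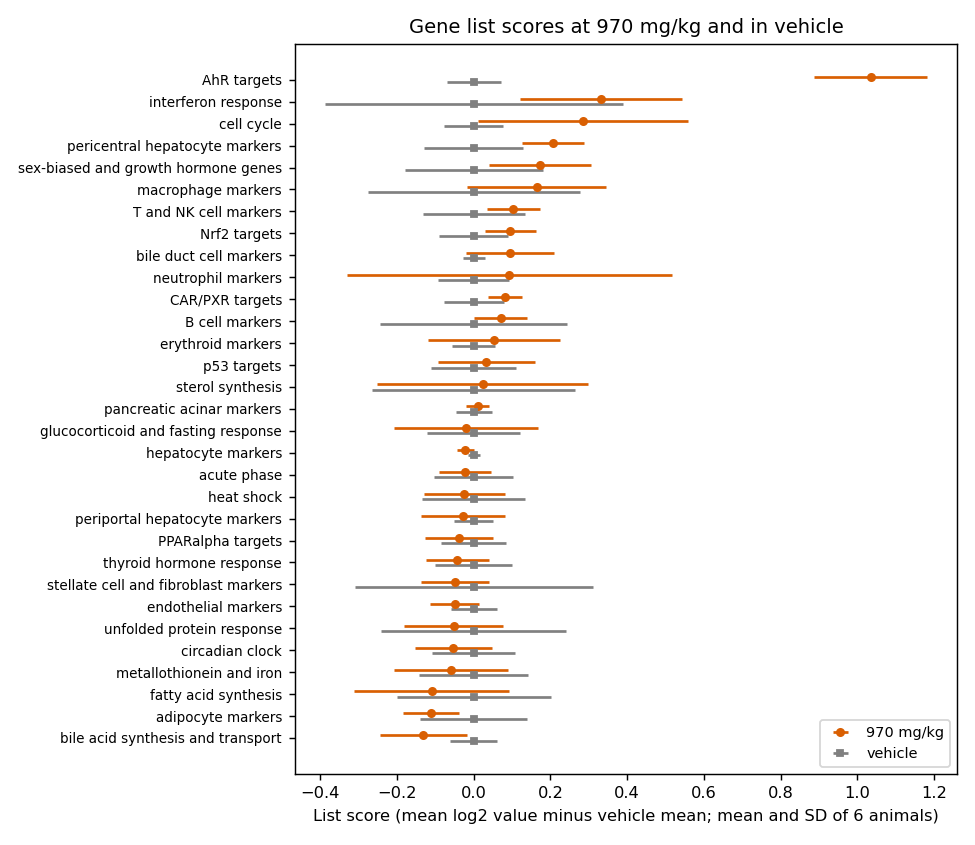
Mean log2 score of each of the 31 gene lists (vertical axis) relative to vehicle (horizontal axis), as the mean and SD of the 6 animals at 970 mg/kg (orange) and of the 6 vehicle animals (grey). The AhR list lies highest, at 1.03, followed by the interferon list at 0.33 and the cell cycle list at 0.28.

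The comparison of 97.1 mg/kg with vehicle gave Cyp1a1 and Cyp1a2 again as the probe sets that rose. Cyp1a1 reached 8.06 ± 1.05 (SD, n = 6), from 6.66 to 9.26 between animals, a log2 fold change of 3.49 (95% interval 2.92 to 4.05), or 11.2-fold, with a limma adjusted p of 6.455e-10. Limma pools the spread of all 6 groups, which gives this Cyp1a1 difference a standard error of 0.28. The 2 groups compared give 0.43 by themselves, so this interval is too narrow. Cyp1a2 reached 13.32 ± 0.10 (SD, n = 6), a log2 fold change of 0.51 (0.38 to 0.63), or 1.42-fold, with a limma adjusted p of 1.520e-05. In both genes 6 of 6 treated animals lay above every vehicle animal (exact permutation p = 0.00216 for each). Of the genes past no threshold, Rap2a had 0.29, Mmp16 -0.39 (adjusted p = 0.346), Nfkbiz -0.64 and Prps2 -0.34. The unadjusted p was under 0.05 for 1684 probe sets. The AhR list rose with Cyp1a1 and Cyp1a2 as the 2 of 8 members that rose (adjusted p = 1.959e-07, and 1.457e-04 with an estimated correlation), and its other 6 members had a median of 0.11 (camera p = 0.197). All 19 sterol synthesis genes measured had values above 0, with a median of 0.23 (Tm7sf2 0.30, Idi1 0.34; adjusted p = 1.433e-06, and adjusted p = 0.414 with an estimated correlation). Heat shock genes had a median of 0.08 with 10 of 13 above 0 (Chordc1 0.22, Dnajb1 0.26; adjusted p = 0.00386, and adjusted p = 0.414 with an estimated correlation). Nrf2 targets had 0.11 with 16 of 19 above 0 (Txnrd1 0.18, Ugdh 0.12; adjusted p = 0.00491, and adjusted p = 0.382 with an estimated correlation). T and NK cell markers had 0.15 with 9 of 12 above 0 (Cd3e 0.19, Nkg7 0.21; adjusted p = 0.0388, and adjusted p = 0.414 with an estimated correlation). The cell cycle list did not pass (median 0.01, adjusted p = 0.418), though its member Mcm4, a DNA replication helicase gene, rose at 0.31 when adjusted over the list alone (limma adjusted p = 0.0184).

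The direct comparison of 970 with 97.1 mg/kg asks whether the responding genes still rose over the last dose step. Cyp1a1 rose by a further 2.75 on the log2 scale (95% interval 2.18 to 3.32) and Cyp1a2 by 0.35 (0.23 to 0.48), and these were the 2 probe sets that passed limma in this comparison. For Cyp1a1 the standard error from these 2 groups by themselves was 0.50, against 0.28 in limma, so its interval is too narrow. The exact permutation p was 0.00216 for each gene. The cell cycle score was higher at 970 than at 97.1 mg/kg by 0.27 (exact permutation p = 0.108), which does not pass. The fold changes at 97.1 and 970 mg/kg share their vehicle arrays and correlated across probe sets at r = 0.573, where simulated data with no dose effect gave 0.489. With the vehicle arrays divided between the doses r was 0.0674, and 25 of 100 simulations gave a covariance as large. The overlap of 2 called genes stood in all 20 divisions of the vehicle arrays, where independent calls would share 1.289e-04.

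At 9.71 mg/kg 0 probe sets passed limma, and 1570 had an unadjusted p under 0.05. Cyp1a1 was higher than vehicle by 0.29 on the log2 scale (exact permutation p = 0.0130, or 0.0223 adjusted over 12 such tests) and Cyp1a2 by 0.13 (exact permutation p = 0.0238, or 0.0357 adjusted), differences chosen for this test after their values were seen. The 12 tests include those of the top 2 doses, all at the smallest possible p, which eases the adjustment. In limma both genes had an adjusted p of 0.978 at 9.71 mg/kg. For Cyp1a1 that fit has a standard error of 0.28, widened by the spread at the top doses, where the 2 groups compared give 0.092. Its limma p therefore says little about a rise of this size. In a fit of the 12 samples compared alone 0 probe sets passed either. Since the exact tests were chosen after the values were seen, a rise at this dose is not established. The smallest p belonged to Kansl1 at 0.38, Spetex2l2 at 0.43 and Tp53bp1 at 0.27, and to Mbp at -1.02, Vps26b at -0.28 and Znf865 at -0.25, none past the threshold. Interferon response genes had a median of 0.34 with 18 of 21 above 0 (Mx2 0.99, Irgm 0.47; adjusted p = 7.312e-06, and adjusted p = 0.818 with an estimated correlation). Macrophage markers had 0.17 with 11 of 12 above 0 (adjusted p = 0.00936, and adjusted p = 0.818 with an estimated correlation), and sterol synthesis genes 0.07 with 17 of 19 above 0 (Insig1 0.61; adjusted p = 0.0487, and adjusted p = 0.889 with an estimated correlation). Of the erythroid markers, Hbb and Alas2, a globin and the red cell heme synthesis enzyme, fell by 0.40 and 0.42 when adjusted over the list alone (limma adjusted p = 0.0334 for both). The erythroid list itself did not pass. It was the only list with such a member at this dose, about what chance gives over 31 lists.

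At 0.97 mg/kg 0 probe sets passed limma and 1526 had an unadjusted p under 0.05. Cyp1a1 had a log2 fold change of 0.16 and Cyp1a2 of 0.11 (exact permutation p = 0.193 and 0.158). Ablim1 (0.33), Bpifb4 (0.30), Ntrk2 (0.32), Kat6b (-0.28), Glyctk (-0.22) and Or6f2 (-0.29) had the smallest p and did not pass. Interferon response genes had a median of 0.30 with 20 of 21 above 0 (Irf7 0.73, Oas1a 0.77; adjusted p = 3.507e-07, and adjusted p = 0.585 with an estimated correlation). Macrophage markers had 0.23 with 12 of 12 above 0 (Clec4f 0.38; adjusted p = 2.531e-04, and adjusted p = 0.585 with an estimated correlation). T and NK cell markers had 0.11 with 11 of 12 above 0 (Klrd1 0.28, Prf1 0.45; adjusted p = 4.090e-04, and adjusted p = 0.244 with an estimated correlation). B cell markers had 0.17 with 6 of 6 above 0 (Cd79b 0.17; adjusted p = 0.0356, and adjusted p = 0.585 with an estimated correlation). Among periportal hepatocyte markers Ass1, a urea cycle gene, rose at 0.16 when adjusted over the list alone (limma adjusted p = 0.0422), and the list did not pass. No other list had such a member at this dose, about what chance gives over 31 lists.

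At 0.1 mg/kg 0 probe sets passed limma and 1384 had an unadjusted p under 0.05. Cyp1a1 had 0.03 and Cyp1a2 had 0.14 (exact permutation p = 0.786 and 0.0974). Ctnna2 (0.31), Klhdc1 (0.25), Lepr (0.33), Mmp16 (-0.36), Psg16 (-0.29) and Sparc (-0.46) had the smallest p and did not pass. Fatty acid synthesis genes had a median of -0.12 with 2 of 20 above 0 (adjusted p = 1.331e-04, and adjusted p = 0.470 with an estimated correlation), and the desaturase genes Scd and Fads2 fell by 0.81 and 0.19 when adjusted over the list alone (limma adjusted p = 0.0355 for both). No other list had such a member at this dose, about what chance gives over 31 lists. Stellate cell and fibroblast markers had -0.19 with 1 of 13 above 0 (Dcn -0.54, Des -0.22; adjusted p = 1.331e-04, and adjusted p = 0.632 with an estimated correlation). Pericentral hepatocyte markers had 0.13 with 7 of 7 above 0 (Glul 0.17; adjusted p = 0.00324, and adjusted p = 0.470 with an estimated correlation). Macrophage markers had 0.17 with 12 of 12 above 0 (adjusted p = 0.00714, and adjusted p = 0.995 with an estimated correlation). The cell cycle list had -0.10 with 3 of 26 above 0 (Mki67 -0.33, Tyms -0.20; adjusted p = 0.0119, and adjusted p = 0.995 with an estimated correlation). In the comparisons of the 3 lowest doses 0 probe sets also passed with variances not moderated across genes.

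Over all 6 groups the limma F test and the slope per dose step each gave 2 probe sets, Cyp1a1 and Cyp1a2. Per step Cyp1a1 rose by 1.19 and Cyp1a2 by 0.16 on the log2 scale (limma adjusted p = 1.648e-07 for both slopes). Melk, a mitotic kinase gene, had a slope of 0.06 and Bicral, Vamp1 and Zfp266 had -0.07, -0.06 and -0.05 (adjusted p = 0.197 for each), not past the threshold. Without vehicle replicate 4, Vamp1 passed (limma adjusted p = 0.00562). Its 2 other probe sets each had a slope of -0.007 in all samples (limma adjusted p of 0.964 or more). With the dose in mg/kg instead of in steps, which weights the highest dose, 15 probe sets passed, all with positive slopes. Besides Cyp1a1 and Cyp1a2, 11 of them name 1 gene, and 4 of these, Aurkb, Ccnb1, Cdk1 and Cdc20, belong to the cell cycle list. The others of the 11 were Cyb5a, St6galnac4 and the mitosis genes Cenpw, Kif22, Smc2, Aspm and Knl1, named here after their values were seen. By dose step the AhR list rose (adjusted p = 1.610e-08, and 2.641e-04 with an estimated correlation). The cell cycle list had 24 of 26 slopes above 0, and 12 members rose when adjusted over the list alone, Mcm4 (0.06) and Ccnb1 (0.11) among them (adjusted p = 1.764e-17, and adjusted p = 0.0832 with an estimated correlation). Of the heat shock list, Bag3 fell by 0.05 per step when adjusted over the list alone (limma adjusted p = 0.0492), and that list did not pass. The adjustment over the list alone does not allow for the 31 lists, so such a member can arise by chance.

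A further 7 lists passed for the dose trend at the preset correlation and none of them at the estimated correlation. Nrf2 targets had 16 of 19 slopes above 0 (Hmox1 0.04; adjusted p = 0.00145, and adjusted p = 0.214 with an estimated correlation). Sterol synthesis genes had 19 of 19 above 0 (adjusted p = 0.00474, and adjusted p = 0.576 with an estimated correlation), and interferon response genes 18 of 21 (adjusted p = 0.00193, and adjusted p = 0.557 with an estimated correlation). CAR and PXR targets had 14 of 18 above 0 (adjusted p = 0.0247, and adjusted p = 0.287 with an estimated correlation). Endothelial markers had 1 of 8 above 0 (Kdr -0.03, Eng -0.02; adjusted p = 0.0272, and adjusted p = 0.214 with an estimated correlation). T and NK cell markers had 7 of 12 above 0 (adjusted p = 0.0327, and adjusted p = 0.371 with an estimated correlation), and pericentral hepatocyte markers 4 of 7 (adjusted p = 0.0443, and adjusted p = 0.371 with an estimated correlation).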

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

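The tests of other groupings of the samples were planned; those weighing explanations for the Cyp1a, cell cycle and interferon patterns were chosen after the results were seen. A sample is listed where its gap to the nearest of its group divided by the group's range exceeded Dixon's 95% critical value. This happened in 20 of 297 groups of 6 animals examined, where chance gives about 1 in 20, or 14.85; among named genes it was 10 of 99.

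Cdkn1a, a p53 target, had a log2 level of 9.31 in replicate 4 at 970 mg/kg, far above the other 5 animals, and the p53 target score of that animal stood apart at 0.28. Cdkn1a is 1 of the 12 measured members of that list, so the score is not a separate observation. Nqo1 was far above its group at 8.96 in vehicle replicate 5 and at 9.75 in replicate 6 at 970 mg/kg. Depp1 was high at 9.45 in replicate 3 at 970 mg/kg, Ephx1 at 12.96 in replicate 2 and Ugt2b1 at 12.38 in replicate 1 of the same dose. Ctnna2 was high at 4.75 in replicate 1 at 0.1 mg/kg. Cyp1a1 was low at 4.18 in replicate 4 at 0.1 mg/kg, Cyp7a1 at 10.52 in vehicle replicate 6 and Prps2 at 5.99 in replicate 2 at 97.1 mg/kg. At 970 mg/kg replicate 6 lay below its group in the interferon score (-0.073), the macrophage score (-0.19) and the acute phase score (-0.15), and replicate 3 lay above it in the neutrophil score (0.94). In vehicle, replicate 5 was low in the neutrophil (-0.17) and erythroid (-0.11) scores, and replicate 1 was high in the metallothionein and iron score (0.28). At 0.97 mg/kg the PPARalpha score was high in replicate 5 (0.16) and the bile acid score low in replicate 2 (-0.20).

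The rise of Cyp1a1 and Cyp1a2 at 970 mg/kg was set against cross-hybridisation between these related genes and against RNA quality. The lower bound of the Cyp1a1 fold, 50.7, is far above any fold of Cyp1a2, so Cyp1a2 transcripts read by the Cyp1a1 probe set cannot give it. In the other direction, the linear rise of Cyp1a2 per unit of Cyp1a1 rise was 3.30 times larger at 97.1 than at 970 mg/kg (95% bootstrap interval 2.09 to 5.78), whereas a fixed share of Cyp1a1 signal would give an equal ratio, unless signals near the top of the scale are compressed. With the beta-actin difference as a covariate the larger of the shifts of the fold changes was 0.236 of its standard error. Treatment with DBDPE, the factor of the design, remains the explanation that these checks leave standing. They do not tell the compound itself from anything else in the dosed material. The comparison with vehicle and the panel that holds both genes were fixed in advance, whereas the checks were chosen after the results were seen.

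The higher cell cycle transcripts at 970 mg/kg were set against 1 deviant animal, low vehicle values, RNA quality and admixed cells. The score of all 6 animals exceeded that of the 18 animals at the 3 lowest doses by 0.37, which argues against low vehicle values, and with the beta-actin covariate the mean fold change was 0.29, which argues against RNA quality. The weight of replicate 3 stays open: without it the score was higher than vehicle by 0.20 (exact permutation p = 0.0671) and higher by 0.27 than the 24 animals at vehicle and the 3 lowest doses (exact permutation p = 4.716e-04), whose dosed groups lie below vehicle. Blood or immune cells stay open too: over 36 animals the score correlated with neutrophil markers at r = 0.341 and rho = 0.0723 (permutation p = 0.223 and 0.698, 0.290 and 0.872 adjusted over 5 relations; r = 0.0233 without the 2 farthest animals) and with macrophage markers at r = 0.296 and rho = 0.311 (permutation p = 0.0570 and 0.0676, 0.285 and 0.338 adjusted; r = 0.316 without the 2 farthest), while S100a8 and S100a9 of neutrophils had log2 fold changes of 0.10 and 0.35 at 970 mg/kg. More dividing liver cells at this dose may be present but remain a hypothesis, since replicate 3 and other cell types stay open.

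The interferon list passed camera at 0.97, 9.71 and 970 mg/kg only at the preset correlation. These comparisons share their vehicle arrays, so the 3 passes are not independent. From 0.1 to 970 mg/kg the mean score lay above vehicle by 0.19, 0.40, 0.36, 0.16 and 0.33, in no dose order. The macrophage score did likewise, by 0.16, 0.21, 0.16, 0.08 and 0.16. Low values in the vehicle animals were therefore not excluded. The smallest exact permutation p of its score over the 3 doses was 0.110, in line with a spread between animals of genes that move together. Over deviations from group means in 36 animals the score followed the macrophage score at r = 0.888 and rho = 0.893 (permutation p = 1.000e-05 for both, the smallest these permutations give, and 2.000e-05 adjusted over 4 relations; r = 0.863 without the 2 farthest). Macrophages that vary in number or activity between livers are therefore a candidate explanation. Lyz2, Clec4f and Cd14, the macrophage markers measured at the highest level, had log2 fold changes of -0.08, 0.28 and 0.23 at 970 mg/kg, and an effect of DBDPE was not separated from it.

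Other splits of the samples into groups of the same sizes, 100 for each comparison with the real one included, gave the following. For probe sets, 1 split reached the real value of 2 at 97.1 mg/kg (highest other 1) and 1 reached 2 in the trend (highest other 0). At 970 mg/kg 4 reached 2 (highest other 151), and in the F test 2 reached 2 (highest other 9). These results met the limit set in advance for each comparison but were not adjusted over comparisons. At 97.1 mg/kg and in the trend no other split reached the real count. At 970 mg/kg and in the F test some splits exceeded it, so the count alone does not exclude chance there. At 0.1, 0.97 and 9.71 mg/kg the real value was 0, which all 100 splits reach (highest others 6, 1 and 31). The splits with 151 and 31 probe sets may reflect genes that move together between animals or a structure that the labels do not name. Neither was tested, and the median of the other splits was 0 at both doses. For lists at the preset correlation chance cannot be excluded. At 0.1 mg/kg 30 splits reached the real 5 (highest other 11), at 0.97 mg/kg 53 reached 4 (highest other 10), at 9.71 mg/kg 68 reached 3 (highest other 11) and at 97.1 mg/kg 49 reached 5 (highest other 10). At 970 mg/kg 11 reached 9 (highest other 12), and for the trend 6 reached 9 (highest other 10).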

How the results depend on the processing

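Lists without Cyp1a1 and Cyp1a2 and the exact permutation test of the list scores were chosen after seeing the data; the other alternatives were planned. Cyp1a1 and Cyp1a2 stayed past the threshold at 97.1 and 970 mg/kg under every alternative run: at 970 mg/kg the log2 fold change lay between 6.03 and 6.39 for Cyp1a1 and between 0.82 and 0.89 for Cyp1a2, and at 97.1 mg/kg between 3.25 and 3.77 and between 0.46 and 0.53. With each sample left out, the number of probe sets stayed at 0 for the 3 lowest doses and 2 at 97.1 mg/kg, and ranged from 2 to 3 at 970 mg/kg, in the F test and in the trend. The added probe set at 970 mg/kg was Vamp1 without vehicle replicate 4 and one that names no gene without vehicle replicate 2 or replicate 6 of the dose. With the dose in mg/kg, which gives the highest dose most of the weight, the trend gave 15 probe sets. That slope also sets the highest dose against all lower groups together, and the cause of the larger count was not tested. The replicate block gave 0, 0, 0, 2 and 2 probe sets at the rising doses.

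With an estimated correlation, and equally with fry, 0 lists passed at 0.1, 0.97 and 9.71 mg/kg, 1 at 97.1 mg/kg, 3 at 970 mg/kg and 1 for the trend. Lists without Cyp1a1 and Cyp1a2 at an estimated correlation gave 0 in all 6 comparisons, and the exact permutation test of list scores gave 0 at each of the 5 doses, where the AhR list at 97.1 and 970 mg/kg had an adjusted p of 0.0671 with the smallest p that 6 against 6 animals allow. The cell cycle list holds neither gene, so leaving them out changed its result at 970 mg/kg through the adjustment over lists alone. At 9.71 mg/kg the mean of a gene's probe sets gave 6 lists and the beta-actin covariate 5; the cause was not tested. With each sample left out, the number of lists ranged from 4 to 6 at 0.1 mg/kg, from 3 to 6 at 0.97, from 1 (vehicle replicate 4) to 8 (vehicle replicate 6) at 9.71, with 7 without vehicle replicate 2 and 5 without replicate 1 or 5 of the dose, from 4 to 9 (vehicle replicate 2) at 97.1, from 6 to 12 at 970 mg/kg and from 5 (vehicle replicate 5) to 11 for the trend. The mean cell cycle fold change at 970 mg/kg lay between 0.20 (without replicate 3) and 0.36 (without replicate 6). Of 2003 values of named genes not past the threshold under the alternatives, 38 had the other sign and 6 passed it, 4 of them for Cyb5a at 970 mg/kg and the others for Vamp1 without vehicle replicate 4. No called value changed sign. Signal over background limits transcripts of low level such as Cyp1a1 in vehicle. Its folds at 97.1 and 970 mg/kg are measured from 4.57 on the log2 scale and may be too small.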

Other observations

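The tests among Bcl6, Cish and Socs2 and of a shared response below the threshold were planned before their results were seen; the tests of the other gene pairs, the bile acid and interferon scores, Cyp1a1 between animals and the cell cycle spread were chosen after. Between animals of a group, genes under pulsatile growth hormone control varied together over 36 animals. Bcl6, a repressor that growth hormone lowers, ran against Cish and Socs2, which growth hormone induces. Its correlation with Cish was r = -0.534 and rho = -0.477 (permutation p = 0.00282 and 0.0112; 0.00329 and 0.0130 adjusted over 7 relations; r = -0.475 without the 2 farthest animals). With Socs2 it was r = -0.746 and rho = -0.730 (permutation p = 2.000e-05 for both, 7.000e-05 adjusted; r = -0.731 without the 2 farthest). With Onecut1, a growth hormone responsive liver factor, it was r = -0.886 and rho = -0.837 (permutation p = 1.000e-05, the smallest these permutations give, 7.000e-05 adjusted; r = -0.852 without the 2 farthest). Cish correlated with Socs2 at r = 0.451 and rho = 0.443 (permutation p = 0.0169 and 0.0181, unchanged by adjustment; r = 0.409 without the 2 farthest) and with Onecut1 at r = 0.582 and rho = 0.580 (permutation p = 9.400e-04 and 0.00132; 0.00132 and 0.00190 adjusted; r = 0.551 without the 2 farthest). Growth hormone pulses caught at different phases are a candidate explanation that these values are consistent with, and hormone levels were not measured.

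Cyp7a1 varied along the same axis. Bcl6 and Cyp7a1 correlated at r = 0.579 and rho = 0.534 (permutation p = 1.300e-04 and 0.00136; 2.275e-04 and 0.00190 adjusted over 7 relations; r = 0.544 without the 2 farthest of 36 animals). The scores of the sex-biased and growth hormone list and of the bile acid list correlated at r = -0.677 and rho = -0.660 (permutation p = 6.000e-05 and 1.900e-04; 1.400e-04 and 4.433e-04 adjusted; r = -0.597 without the 2 farthest). The bile acid score was -0.15 at 97.1 mg/kg and -0.13 at 970 mg/kg relative to vehicle (exact permutation p = 0.00649 and 0.0303, 0.101 and 0.278 adjusted over 31 lists, where a lone list cannot go below 0.0671), with 5 of 6 animals below every vehicle animal at each dose, where the list medians were -0.04 and -0.01. These score results rest on Cyp7a1 and Nr0b2. Without them the score of the other 13 members differed from vehicle by -0.03 at 97.1 mg/kg (exact permutation p = 0.214) and by -0.0013 at 970 mg/kg (exact permutation p = 0.974), and its correlation was r = -0.0362 and rho = -0.0286 with the growth hormone list (permutation p = 0.850 and 0.883) and r = 0.0471 and rho = 0.0963 with Bcl6 (permutation p = 0.790 and 0.600). Cyp7a1 had -0.90 and -1.07 there, but also -0.92 at 9.71, -0.35 at 0.97 and -0.68 at 0.1 mg/kg. Nr0b2, a bile acid responsive repressor, had -0.88 and -0.89 at the top doses and 0.12, -0.11 and -0.49 at 9.71, 0.97 and 0.1 mg/kg, and no value of either gene passed the threshold over the list alone. Among the 12 animals at 97.1 and 970 mg/kg the bile acid score followed Cyp1a1 at r = 0.667 and rho = 0.741 (permutation p = 0.00972 and 0.00893; 0.0146 and 0.0134 adjusted over 3 relations; r = 0.760 without the 2 farthest), and without Cyp7a1 and Nr0b2 at r = 0.212 and rho = 0.238 (permutation p = 0.474 and 0.457). Adjusted over these 3 relations without the 2 genes, every p was 0.850 for r and 0.883 for rho, and r without the 2 farthest animals was -0.115, 0.166 and 0.216.

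Cyp1a1 differed between animals of 1 dose, and animals in which more compound reached the liver may have more of both genes. Over deviations from the means of the 12 animals at 97.1 and 970 mg/kg, Cyp1a1 and Cyp1a2 correlated at r = 0.799 and rho = 0.804 (permutation p = 0.00328 and 0.00373; 0.00984 and 0.0112 adjusted over 3 relations; r = 0.819 without the 2 farthest), which this needs but which any shared inducer would give. The same animals gave r = -0.131 and rho = -0.196 between Cyp1a1 and the cell cycle score (permutation p = 0.708 and 0.569; 0.708 and 0.569 adjusted; r = 0.0393 without the 2 farthest), so those with most Cyp1a1 were not shown to have most cell cycle transcripts.

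The cell cycle score spread more between animals at the top doses, with a variance 12.2 times that of the other groups, rank 1 of the 31 lists. Since the list was picked for this ratio, each permutation of the animals kept the highest ratio over the 31 lists (median 2.93). The one-sided permutation p was 6.000e-05, so for this cut between doses chance alone is unlikely to give such a spread. The cut was also chosen after the results were seen, and the p does not allow for that choice. Whether the spread rises with the mean level alone was not tested. Replicate 3 at 970 mg/kg had the highest score, 0.70, followed by replicate 3 at 97.1 mg/kg with 0.48. The animal numbered 3 was also the highest of its group in vehicle (0.11), at 0.1 mg/kg (0.02) and at 9.71 mg/kg (0.04). At 0.97 mg/kg it was not (-0.10). The labels do not say what the number stands for, and a link between the number and this score was not tested. Over the 36 animals the score had correlations with T and NK cell markers of r = 0.179 and rho = 0.229 (permutation p = 0.232 and 0.189, 0.290 and 0.474 adjusted over 5 relations; r = 0.305 without the 2 farthest), with B cell markers of r = 0.170 and rho = 0.160 (permutation p = 0.195 and 0.357, 0.290 and 0.595 adjusted; r = 0.226 without the 2 farthest) and with erythroid markers of r = 0.106 and rho = -0.0077 (permutation p = 0.663 and 0.970, both unchanged by adjustment; r = -0.330 without the 2 farthest), none past the threshold.

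Besides macrophages, the interferon score followed T and NK cell markers over the 36 animals at r = 0.743 and rho = 0.796 (permutation p = 1.000e-05 for both, the smallest these permutations give, 2.000e-05 adjusted over 4 relations; r = 0.714 without the 2 farthest). With B cell markers r was 0.127 and rho 0.137 (permutation p = 0.511 and 0.476; 0.511 and 0.476 adjusted; r = 0.0529 without the 2 farthest), and with neutrophil markers r was -0.182 and rho -0.207 (permutation p = 0.206 and 0.225; 0.274 and 0.2998 adjusted; r = -0.0761 without the 2 farthest).

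A broad shared response below the threshold was the hypothesis tested on the fold changes at 97.1 and 970 mg/kg. With the vehicle arrays divided 3 and 3 between the doses, their covariance over 31040 probe sets was 0.00102, and 25 of 100 simulations without a dose effect gave as much, so no such response was detected.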
